A study of Mus musculus with 15 samples.

How the data were processed

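The series measured chromatin by ChIP-seq, in which DNA bound by an antibody's target is sequenced, in mouse macrophages. Bone marrow-derived macrophages (BMDMs) came from C57BL/6 mice of 12 to 16 weeks and were differentiated for 7 days, per the labels' protocols. RAW264.7 is a macrophage-like mouse cell line, which the labels place on a BALB/c background. GPS2 is a subunit of the NCoR/SMRT corepressor complex. Antibodies against its N-terminal and its C-terminal part were used, after crosslinking with 2 mM DSG for 30 min and then 1% formaldehyde for 10 min, per the labels' protocols. The histone marks H3K27ac, found at active enhancers and promoters, and H3K4me3, found at promoters, were measured in wild-type (WT) and GPS2-knockout (GPS2-KO) BMDMs after 1% formaldehyde for 10 min.

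The values are raw tag counts that the authors deposited in 1 table of 96693 windows of 1000 bp, which held whole numbers in all 13 count columns. Tags were processed with Bowtie2 2.2.3 and HOMER on the mouse build mm9, per the submitters' processing notes. How the windows were chosen, how duplicate tags were handled and the settings of either tool are not given in the sources used here. The deposited table separates its fields by spaces and its text fields also hold spaces, so each line was read from both ends; all 96693 lines were read and 0 were left unread. Each window carries the nearest gene, its distance to that gene's start and an annotation in the table, and all gene names and coordinates are the table's own. Of the 96693 windows, 59673 (61.7%) overlapped another one, so neighbouring windows share tags, and 64094 windows remained when overlapping windows were thinned from the highest peak score down.

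The series lists 15 samples, and 13 had a column. GPS2 ChIP of GPS2-KO BMDMs and input DNA of WT BMDMs were not analysed here. The RAW264.7 input therefore stood in as the control of the BMDM GPS2 library, and the planned comparison with GPS2-KO tags was left out. Groups and replicate numbers were taken from the sample titles.

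Each histone mark was compared between 2 GPS2-KO and 2 WT libraries in a fit of its own. edgeR had been planned as the main test before the data were examined and was not used, because the space-separated layout kept the table from being registered as plain counts. limma voom 3.58.1 in R 4.3.3 took its place, on the raw tag counts, with TMM factors computed from their published definition (trimming 30% of log ratios and 5% of levels). Windows were kept when at least 2 libraries reached the CPM (counts per total, scaled to the same depth) that equals 10 tags in the median library and the total was at least 15 tags. p-values were adjusted by Benjamini-Hochberg (BH), with a threshold of 0.05. Levels are given as CPM after TMM, as mean ± SD. Tables were read with Python 3.11.15 and pandas 2.3.3, and plots were drawn with matplotlib 3.10.9.

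A window was counted as GPS2-enriched when a GPS2 library had at least 10 tags and at least 4-fold the CPM of the RAW264.7 input, with 1 tag added to each. With 1 library per group no test was made. Ratios printed for single windows have no tag added and carry exact 95% intervals from the 2 tag counts; these intervals cover counting error only. Against an input of 0 tags the fold was computed against a floor of 3 tags. Overlaps between GPS2 libraries were set beside the overlap of independent lists and beside 100 simulations in which every library was drawn from the input alone, since all lists share that input. The N-terminal and C-terminal libraries of RAW264.7 were compared by limma voom with 1 residual degree of freedom, the lone C-terminal library being assumed to vary like the N-terminal pair. Shares of annotations and gene lists were compared by Fisher's exact test, two-sided, over non-overlapping windows with enough tags to pass. The test takes windows as independent, though several can belong to 1 gene, and the other windows were not matched on histone level.

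The 23 gene lists were fixed before the data were examined. They covered chemokines and chemokine receptors, inflammatory cytokines and effectors, the TLR and NF-kappaB pathway, AP-1 and immediate-early factors, interferon-stimulated genes, LXR targets and cholesterol efflux, sterol biosynthesis and uptake, PPARgamma and alternative activation, scavenging and phagocytosis receptors, macrophage identity, corepressor complex subunits, nuclear-encoded mitochondrial genes, glycolysis and hypoxia response, antigen presentation, cell cycle and common reference genes. They also covered markers of neutrophils, B cells, T and NK cells, dendritic cells, stromal cells and fibroblasts, osteoclasts, and erythroid cells and megakaryocytes. Each list took the windows whose nearest gene was a member, at any distance from its start. Lists were tested by fry, which asks whether a list's windows move on balance one way, and by camera, which compares a list with all other windows, with a preset correlation of 0.01 and with an estimated correlation; p-values were adjusted over the 23 lists of 1 mark.

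The named windows followed a rule set before the data were examined. It took the windows of Gps2, windows past the threshold, the 5 of smallest p per direction where fewer than 10 passed, and the window nearest the start of Ccl2, Ccl7, Il1b, Il6, Tnf, Nos2, Abca1, Abcg1 and Pparg. For GPS2 it took the 10 BMDM windows with the highest lower bound, the 10 RAW264.7 windows with the highest least enrichment, and list members enriched in both cell types. The list members with the smallest unadjusted p that are named beside the lists, and windows of the chemokine cluster, were picked after their values were seen.

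The fits were tested on simulated data drawn from the real means and from the average spread of each level class, with 200 windows changed. Windows of a class shared that spread and libraries were drawn independently. Shifts shared by replicate number were left out, so the recovered shares may overstate those of the real fits. For H3K27ac, over 81339 windows, 8.96% of windows changed 1.5-fold were recovered, 43.3% of those changed 2-fold and 71.2% of those changed 4-fold, with 9 false calls. For H3K4me3, over 40581 windows, these shares were 40.3%, 44.8% and 56.1%, with 3 false calls. For the N-terminal against the C-terminal antibody, over 86857 windows, they were 0%, 8.96% and 50%, with 0 false calls. Alternatives covered the scaling, the filter, the test, the replicate block, the left-out replicates, the fold and tag thresholds and the overlap of windows. A histone fit that leaves out 1 library has 1 library in that genotype, so its spread comes from the other genotype's pair alone.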

Results

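The deposited counts described where ChIP of the corepressor subunit GPS2 was enriched over input in macrophages. They also described how 2 histone marks differed between GPS2-KO and WT BMDMs in basal conditions. H3K27ac and H3K4me3 had 2 libraries per genotype. GPS2 was measured with the N-terminal antibody in 1 library of WT BMDMs and 2 of RAW264.7 cells, and with the C-terminal antibody in 1 library of RAW264.7 cells, beside 1 RAW264.7 input. Tags inside the windows came to 16.25 and 13.65 M (mega) for H3K27ac in WT, 15.4 and 13.82 M in GPS2-KO, 13.93 and 14.26 M for H3K4me3 in WT, and 14.42 and 8.913 M in GPS2-KO. The GPS2 libraries were far shallower, with 1.786 M tags in BMDMs, 2.225 and 2.383 M for the N-terminal antibody in RAW264.7, 1.776 M for the C-terminal antibody, and 1.151 M for the input. Of the windows, 40.8% lay in introns, 36% between genes and 13.7% at promoters. Replicates of a group differed by more than counting noise, with a chi-square per degree of freedom of 1.29 for the N-terminal pair and 2.62 to 5.1 for the histone pairs, so none was counted as a repeat of another. Nothing in the labels says that replicates came from separate animals or cultures, so the p-values measure the spread between these samples, which may be technical.

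The first question was whether loss of GPS2 altered H3K27ac. At the windows nearest their starts, the monocyte chemokine genes Ccl2 and Ccl7 carried more H3K27ac in both GPS2-KO libraries than in either WT library, although no single window passed the test. At Ccl2 (chromosome 11, 81848761 to 81849761, intron 1, mm9) the level was 5.03 ± 1.22 CPM in WT and 8.4 ± 1.51 in GPS2-KO (SD, n = 2), a log2 fold change of 0.75 (SE 0.25). At Ccl7 (chromosome 11, 81858868 to 81859868, intron 1) it was 8.39 ± 4.05 in WT and 16.5 ± 5.14 in GPS2-KO, a log2 fold change of 1.04 (SE 0.32). Itgam, which encodes the integrin subunit CD11b, had 21.3 ± 0.239 in WT and 32.9 ± 1.12 in GPS2-KO in its intron 1 (chromosome 7, 135206999 to 135207999), a log2 fold change of 0.63. Inside Pparg, the gene of a lipid-sensing nuclear receptor, a window 48268 bp past the start had 18.2 ± 1.21 in WT and 12.5 ± 0.948 in GPS2-KO, a log2 fold change of -0.56.

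The 2 windows at the start of Gps2 itself showed no difference beyond replicate spread. They had log2 fold changes of -0.09 (SE 0.11; chromosome 11, 69727404 to 69728404) and 0.09 (SE 0.11; 69727085 to 69728085). The deleted part of the gene is not given in the sources used here, so these windows do not check the genotype labels. Among the fixed genes, the cytokine genes Il1b, Il6 and Tnf had log2 fold changes of 0.37 (SE 0.3), 0.3 (SE 0.34) and -0.12 (SE 0.16) at their starts. Nos2, the inducible nitric oxide synthase, had 0.5 (SE 0.48) at a level of 0.789 CPM in WT. The cholesterol exporters Abca1 and Abcg1 had 0.16 (SE 0.14) and -0.27 (SE 0.29), and the start of Pparg had -0.24 (SE 0.11).

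Of 81339 windows tested for H3K27ac, limma voom with BH adjustment called 0, limma-trend called 0, and the smallest adjusted p by limma voom was 0.989. A fit with replicate number as a block called 3720, 1036 higher and 2684 lower, although no label pairs libraries by number. At an unadjusted p under 0.05 the fit without a block had 3367 windows (4.14%), 1315 higher and 2052 lower in GPS2-KO. Scaling by column totals alone turned this split to 1738 higher and 1325 lower. Besides Itgam, the windows of smallest p on the higher side were weak ones near Mdm1 (log2 fold change 2.14), Mir129-1 (3.12), Slc25a15 (2.25) and Ccdc162 (1.91), with 0.168 to 1.21 CPM in WT. On the lower side they lay near 1700054M17Rik (-0.69), Zfpm1 (-0.83), Crybb3 (-0.97), the promoter of Fam26f (-0.66) and C030006K11Rik (-0.78), with 16.7 to 31.9 CPM in WT. Fold changes moved with the level, from a median of 0.3 in the weakest of 10 level classes to -0.06 in the strongest. Leaving out WT replicate 1 or WT replicate 2 raised the number of calls to 7 and 168; leaving out either GPS2-KO replicate gave 0.

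The chemokine list held the most H3K27ac windows at an unadjusted p under 0.05 on the higher side, 23 against 9 lower among 155 windows. Nearly all of the higher windows were nearest to Ccl2, Ccl7 or Ccl12 and lay in the stretch described below, where many overlap. The median log2 fold change over the list was 0.006, so these counts do not show a rise of chemokine genes as a class. In this list a window near Ccl12 (13.4 ± 4.35 in WT and 20.3 ± 0.363 in GPS2-KO, log2 fold change 0.67) was higher. A window of the chemokine receptor gene Ccr2 (7.19 ± 0.468 and 4.2 ± 0.412, log2 fold change -0.77) was lower. Across the stretch that holds Ccl2, Ccl7, Ccl11, Ccl12 and 2 windows of Ccl8 (chromosome 11, 81818086 to 81953815), which was chosen after its values were seen, all 34 tested windows had a log2 fold change above 0, with a median of 0.69 (quartiles 0.54 and 0.85), and 25 had an unadjusted p under 0.05. In the inflammatory cytokine list 9 of 149 windows were higher and 1 lower at an unadjusted p under 0.05. The higher ones included Il1a at its start (1.86 ± 0.0972 in WT, 3.32 ± 0.22 in GPS2-KO, log2 fold change 0.82) and a window near Mmp9 (1.25). In the PPARgamma list 3 of 191 windows were higher and 19 lower. The lower ones included Ppard (-0.63) and a window 18409 bp from the start of Clec10a (-0.45), and the higher ones Mrc1 (0.42).

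**Figure D1:**
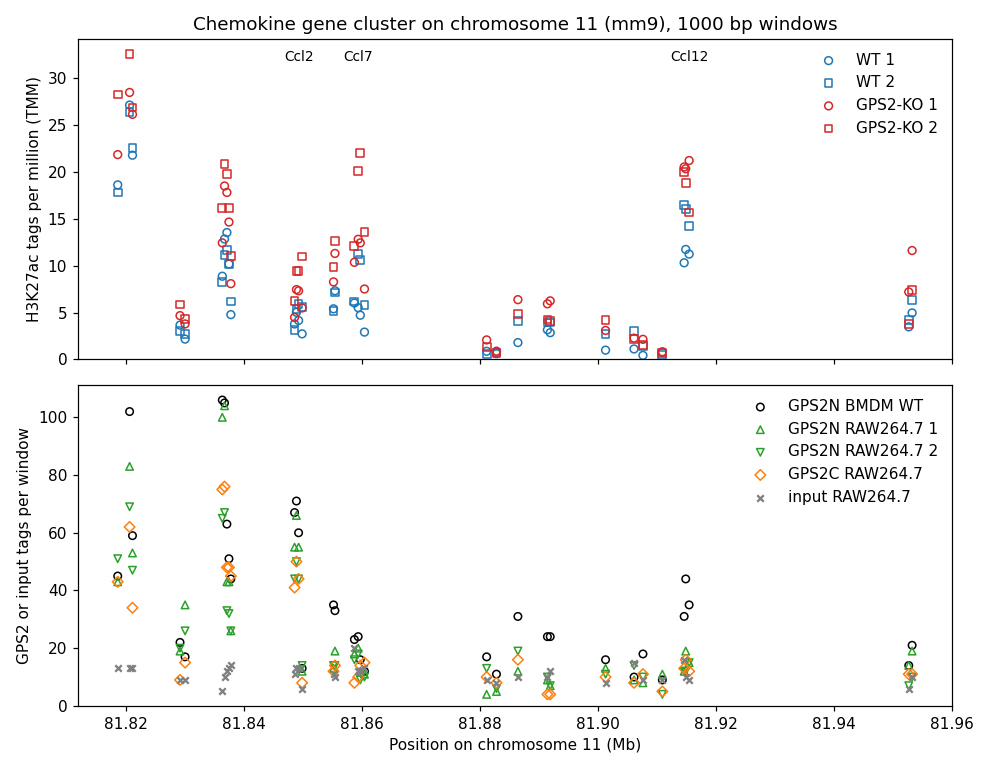
H3K27ac CPM in each of the 4 BMDM libraries (top) and GPS2 or input tags (bottom) in the 34 tested windows of the chemokine stretch, by position in Mb on chromosome 11. GPS2-KO points lie above WT points in most windows, and the window at 81835822 holds 106 GPS2 tags in BMDMs against 5 input tags.

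Over all windows tested for H3K27ac 4.14% had an unadjusted p under 0.05, fewer than that threshold would pass with no change. Counts in a list alone therefore do not show that it moved. In the TLR and NF-kappaB list 1 of 239 windows was higher and 14 lower at that threshold. Examples were an intronic window of Tnip1 (16.5 ± 0.583 in WT, 12.1 ± 0.279 in GPS2-KO, log2 fold change -0.44) and a window at -46514 bp from Tnfaip3 (24.8 ± 1.08 and 20.1 ± 0.429, -0.31). Both genes encode inhibitors of NF-kappaB signalling. The LXR list had 4 higher and 7 lower among 148 windows. Mertk (25.1 ± 1.86 and 17.2 ± 0.755, -0.55) and the LXR gene Nr1h3 (-0.43) were lower, and an intronic window of Abca1 (0.6) and one at Apoe (0.46) higher. The macrophage identity list had 5 higher and 10 lower among 268 windows, with Itgam higher. Windows in Lyz2 (44.4 ± 2.83 and 33.4 ± 2.94, -0.42) and Mitf (-0.42), and a window at -20302 bp from Cebpa (-0.36), were lower. With column totals alone the counts higher and lower were 1 and 7 for the TLR and NF-kappaB list, 6 and 5 for the LXR list, and 6 and 7 for macrophage identity. They were 24 and 5 for chemokines, 5 and 15 for the PPARgamma list, 14 and 6 for AP-1 and immediate-early genes, and 2 and 2 for cell cycle genes. The counts also moved with the libraries kept: without GPS2-KO replicate 1 they were 4 and 4 for the TLR and NF-kappaB list, 2 and 2 for inflammatory cytokines, 7 and 10 for the PPARgamma list and 5 and 4 for the LXR list. Without WT replicate 1 they were 4 and 25 for the LXR list and 0 and 14 for interferon-stimulated genes. Chemokine windows were 16 to 27 higher and 2 to 20 lower over the 4 fits that left out 1 library. AP-1 and immediate-early genes had 12 higher and 10 lower among 425 windows. These were led by intergenic windows at -493870 bp from Klf4 (1.26) and at -14189 bp from Nr4a1 (-0.7). Of 163 scavenging receptor windows 4 were higher, with the Fc receptor genes Fcgr3 (0.44) and Fcgr2b (0.65), and 2 lower, with Lrp1 (-0.29). Of 156 cell cycle windows 2 were higher and 5 lower, with a window 20100 bp from the start of Cdkn1a at 0.88 and Ccnd3 at -0.52. Reference genes had 2 higher and 1 lower among 93 windows.

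Counts of higher and lower windows at an unadjusted p under 0.05 were 2 and 1 for interferon-stimulated genes, 0 and 2 for sterol genes, 2 and 3 for corepressor subunits, 1 and 1 for mitochondrial genes, 1 and 2 for glycolysis, and 1 and 2 for antigen presentation. For markers of other cell types they were 0 and 0 for neutrophils, 2 and 1 for B cells, 1 and 4 for T and NK cells, 0 and 1 for dendritic cells, 3 and 0 for stromal cells, 1 and 2 for osteoclasts, and 0 and 0 for erythroid cells. Stromal markers varied more between libraries of 1 genotype than between genotypes: their median deviation was 0.26 and -0.6 in the WT libraries and 0.57 and -0.21 in the GPS2-KO libraries, and their median log2 fold change was 0.24, 0.763 without WT replicate 1 and -0.101 without WT replicate 2.

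In the fit without a block none of the 23 lists had a window called, 0 over all windows and 0 adjusted over the list alone by limma voom with BH. None passed fry in that fit (smallest adjusted p 0.861). The list-alone result depended on the libraries kept: adjusted over the list alone by limma voom with BH, chemokine windows called were 4 higher without WT replicate 1, 11 higher without GPS2-KO replicate 1, and 15 higher and 9 lower without WT replicate 2. Fits that kept 1 WT library also called windows over the list alone in the LXR, TLR and PPARgamma lists. Their spread comes from the GPS2-KO pair alone. Macrophage identity had 1 higher with column totals and 1 with loess scaling. camera with the preset correlation called the TLR and NF-kappaB list lower (median log2 fold change -0.09, adjusted p = 0.00531), macrophage identity lower (-0.07, adjusted p = 0.00917) and stromal markers higher (adjusted p = 2e-04). With an estimated correlation the adjusted p was 0.817 for each of these lists. After loess scaling, added once fold changes were seen to move with the level, the preset adjusted p was 0.0702, 0.485 and 0.112. In the PPARgamma list median and mean differed in sign (-0.025 and 0.014), as in the corepressor list (-0.041 and 0.021), while camera pointed lower for both without passing (adjusted p = 0.408).

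**Figure D2:**
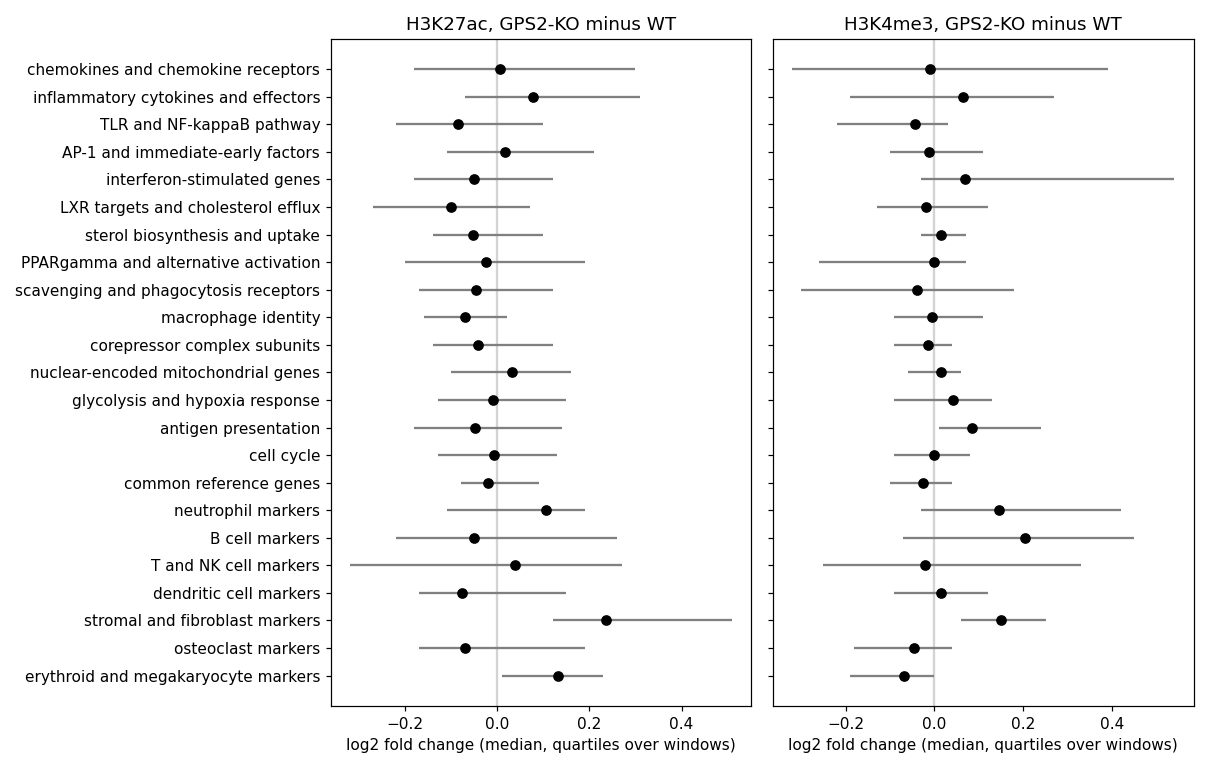
Median log2 fold change, GPS2-KO minus WT, for each of the 23 gene lists in H3K27ac (left) and H3K4me3 (right), with bars from the lower to the upper quartile over windows. Stromal markers have the highest H3K27ac median, 0.24, and the medians of most other lists lie close to 0.

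For H3K4me3, the promoter-side mark, the same chemokine genes again had higher values in GPS2-KO without passing the test. Ccl7 had 3 ± 1.63 CPM in WT and 6.84 ± 0.928 in GPS2-KO (SD, n = 2), a log2 fold change of 1.26 (SE 0.41), and Ccl2 had 2.68 ± 0.983 and 4.76 ± 0.772, a log2 fold change of 0.83 (SE 0.39). The Fc receptor gene Fcgr3 had 14.3 ± 0.888 in WT and 23.4 ± 2.01 in GPS2-KO (chromosome 1, 172987083 to 172988083, intron 3; log2 fold change 0.75), and the scavenger receptor gene Stab1 had 14.8 ± 1.99 and 24.4 ± 0.394 (0.72). In the other direction, the lysozyme gene Lyz2 had 64.5 ± 1.5 in WT and 43.2 ± 7.74 in GPS2-KO in its intron 1 (chromosome 10, 116717840 to 116718840), a log2 fold change of -0.62 (SE 0.12).

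The Gps2 windows had H3K4me3 log2 fold changes of -0.14 (SE 0.1) and 0.08 (SE 0.09). At the fixed genes these were -0.22 (SE 0.42) for Il6, -0.03 (SE 0.1) for Tnf, -1.81 (SE 1.05) for a Nos2 window with 0.814 CPM in WT, -0.06 (SE 0.15) for Abca1, -0.17 (SE 0.2) for Abcg1 and -0.09 (SE 0.09) for Pparg. No window of Il1b had enough H3K4me3 tags to be tested. The remaining windows of smallest p were those of Cpm (3.15, from 0.212 CPM in WT), Pcdhac2 (0.91) and Tmcc1 (1.41) on the higher side. On the lower side they were those of Kcnn4 (-0.4), Cyb5r2 (-2.97), Gpr162 (-0.4) and Zfp395 (-2.35).

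Of 40581 windows tested for H3K4me3, limma voom with BH adjustment called 0, as did limma-trend, while a replicate block called 30 (20 higher, 10 lower). At an unadjusted p under 0.05 the fit without a block had 454 windows (1.12%), 221 higher and 233 lower. Without GPS2-KO replicate 1 these became 2021 higher and 529 lower, and without GPS2-KO replicate 2 they became 1948 higher and 963 lower. In the fit of all 4 libraries without a block no list had a window called, 0 also when adjusted over the list alone. There the smallest adjusted p by limma voom with BH was 0.0522 for scavenging receptors, led by Fcgr3 and Stab1. With loess scaling 2 scavenging windows higher and 2 macrophage identity windows lower were called over the list alone, and without WT replicate 2 there were 7 chemokine windows and 6 interferon windows higher. At an unadjusted p under 0.05 there were 4 higher and 4 lower among 58 chemokine windows, with Ccr2 (-0.97) among the lower ones. There were 2 and 2 in the PPARgamma list, with Mrc1 at 1.36 and Cd36 at -0.86, 1 and 4 in the TLR list, with Tlr9 at -0.59, and 1 and 3 in macrophage identity, with Itgam at 0.76 and Lyz2 lower. The counts were 3 and 0 for AP-1 genes, 0 and 1 for inflammatory cytokines (Nlrp3, -0.31), 3 and 0 for scavenging receptors, 0 and 1 for reference genes, 1 and 0 for neutrophil markers, and 0 and 1 for T and NK cell markers (Cd28, -0.65). They were 0 and 0 for the interferon, LXR, sterol, corepressor, mitochondrial, glycolysis, antigen presentation, cell cycle, B cell, dendritic, stromal, osteoclast and erythroid lists. camera with the preset correlation called the TLR and NF-kappaB list lower (median log2 fold change -0.04, adjusted p = 0.00353), which was lost with an estimated correlation (adjusted p = 0.867); none passed fry (smallest adjusted p 0.999).

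GPS2 in WT BMDMs was strongly enriched over the RAW264.7 input upstream of Ccl2 and at Tbl1xr1. A window at -12757 bp from the start of Ccl2 (chromosome 11, 81835822 to 81836822, intergenic) had 106 GPS2 tags in BMDMs against 5 in the input, a depth-scaled ratio of 13.7 (95% interval 5.67 to 42.9), and 100 and 65 tags with the N-terminal and 75 with the C-terminal antibody in RAW264.7. The first exon of Tbl1xr1, which encodes another corepressor subunit (chromosome 3, 21975198 to 21976198, 5' UTR), had 81 tags in BMDMs and a ratio of 17.4 (5.75 to 86.1). A window at -178583 bp from Jun, an AP-1 subunit gene (chromosome 4, 94896996 to 94897996), had 66 tags and a ratio of 21.3 (5.66 to 179). The promoter of Abca1 (chromosome 4, 53172417 to 53173417) had 85 tags and a ratio of 6.09 (3.06 to 13.8). The iron-storage gene Fth1 had 131 tags and a ratio of 12.1 (5.69 to 30.6).

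In all, 996 windows near 703 genes were GPS2-enriched in BMDMs. Of the 557 that did not overlap, 39.1% (exact 95% interval 35.1 to 43.3%) lay within 1000 bp of a gene start, against 23.9% of the other 50676 windows (odds ratio 2.04, Fisher's exact adjusted p = 4.81e-14). Among the 23 lists, corepressor subunit genes held more enriched windows than other genes, 6 of 86 in 4 genes (odds ratio 6.89, Fisher's exact adjusted p = 0.00833). Windows of 1 gene are not independent, so this p-value may be too small. Inflammatory cytokines had 5 of 109 and AP-1 genes 8 of 259, each with an adjusted p of 0.0601 by Fisher's exact test. Macrophage identity had 5 of 173 (adjusted p = 0.237) and the LXR list 3 of 87 (adjusted p = 0.32). The chemokine list had 2 of 96, cell cycle 3 of 95, scavenging receptors 2 of 93, and the TLR, sterol and reference lists 1 each. Among these non-overlapping windows the interferon, PPARgamma, mitochondrial, glycolysis and antigen presentation lists and all markers of other cell types had 0; enriched windows of the mitochondrial list members Cox4i1 and Tfam were not among the windows counted. Near the fixed genes, the highest BMDM window had a ratio of 4.73 (2.74 to 8.73) for Il6, at -64681 bp from its start, 3.87 (1.13 to 20.5) for Nos2, 3.38 (1.81 to 6.89) for Abcg1, 2.58 (1.1 to 6.99) for Pparg and 2.13 (1.02 to 4.84) for Ccl7. The ratio was 1.8 (0.851 to 4.16) for Il1b and 1.25 (0.677 to 2.39) for Tnf, and Gps2 itself had 0.703 (0.284 to 1.76).

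Some of these windows rest on the stand-in input. Against the median window of the BMDM library itself, with no input, 1037 windows reached 4-fold, and 313 of these were among the 996. Of the 996, 266 had fewer than 3 input tags and 95 had fewer than 10 tags over the 3 RAW264.7 GPS2 libraries together. The promoter of Nlrp1b, an inflammasome sensor gene that differs between mouse strains (chromosome 11, 71043888 to 71044888), had 47 GPS2 tags in BMDMs, at least 10.1-fold over the input floor (exact lower bound 7.89), with 0 input tags and 4, 0 and 0 tags in the RAW264.7 GPS2 libraries. Windows of Nlrp1c-ps (36 BMDM tags, at least 7.73-fold over the floor, exact lower bound 5.97) and Skint3 (32 tags, at least 6.87-fold, exact lower bound 5.27) had 0 tags in every RAW264.7 library, and one near G530011O06Rik on the X chromosome had 85 tags and 1 input tag (54.8, 9.57 to 2190). The other BMDM windows with the highest lower bounds lay near D130058E03 (ratio 14.7, 5.53 to 55) and Tsnax (16.8, 5.52 to 83).

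In RAW264.7 cells the question was whether antibodies against both ends of GPS2 enrich the same regions. The windows named here were picked for the highest least enrichment over the 3 libraries. Their enrichment by both antibodies therefore follows from the rule and does not answer the question. The costimulatory ligand gene Tnfsf9 (chromosome 17, 57244433 to 57245433, exonic) was enriched by both, with ratios of 14 (3.68 to 118) and 14 (3.71 to 118) for the N-terminal and 13.3 (3.45 to 113) for the C-terminal antibody. Zc3h12a, which encodes an RNase that degrades cytokine mRNAs, had ratios of 10.7 (3.49 to 53.3), 10.9 (3.59 to 54.4) and 10.8 (3.49 to 54.2) in a window at -17486 bp from its start. The promoter of Tfam, a mitochondrial transcription factor gene, had 18.6 (3.14 to 756), 19.3 (3.27 to 782) and 15.6 (2.54 to 640). The start of Pafah1b1 had 11.9 (3.11 to 101), 13.5 (3.57 to 114) and 13.9 (3.63 to 119). Windows nearest to Dhx34, Mir7009, Tomm20 (64078 bp from its start) and Irf2bp2 (27923 bp) had ratios between 12.6 and 25.9 on 1 or 2 input tags. Their lower bounds were 2.67 to 5.33. At Tm2d3, with 0 input tags, the 3 libraries lay at least 4.66-fold, 4.67-fold and 4.97-fold over the floor, and at Pola1 at least 3.1-fold, 2.74-fold and 3.02-fold. The exact lower bounds, which also allow for chance in the GPS2 tags, were 3.53, 3.56 and 3.73 for Tm2d3 and 2.27, 1.99 and 2.15 for Pola1.

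Per library 537 and 528 windows were enriched with the N-terminal and 658 with the C-terminal antibody, and 253 in all 3. The N-terminal replicates shared 327, and the C-terminal library shared 341 and 334 with them. Independent lists of these sizes would share 2.93, 3.65 and 3.59 windows, and 0.02 for all 3. Simulated libraries with no enrichment, judged against the same input, shared 202.6, 162.6 and 169.1, and 123.3 for all 3, so part of each overlap may come from low input counts. The same simulations gave 320.6, 335 and 296.8 enriched windows per RAW264.7 library and 302 in the BMDM library. Over all 96693 windows, tags correlated by Spearman's rho of 0.88 between the N-terminal replicates and 0.85 between the antibodies, across windows that are not independent replicates. Of the 119 non-overlapping windows enriched in all 3, 52.1% (exact 95% interval 42.8 to 61.3%) lay within 1000 bp of a gene start, against 28.1% of the others (Fisher's exact adjusted p = 4.6e-07). AP-1 and immediate-early genes held 5 of 217 such windows in 4 genes (odds ratio 7.61, adjusted p = 0.0159 by Fisher's exact test), again with windows of 1 gene taken as independent. Among non-overlapping windows the chemokine, inflammatory, macrophage identity, glycolysis and cell cycle lists had 1 window each and the other lists 0. Counts over all windows are higher, since enriched windows of Tbl1xr1, Lrp1, Cox4i1, Tfam and Actb were not among those counted.

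**Figure D3:**
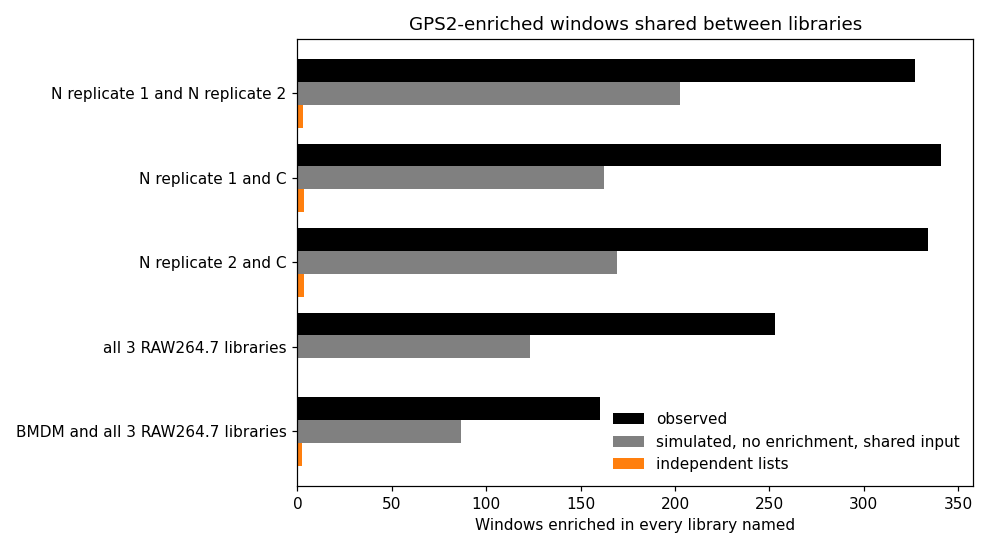
Number of windows enriched for GPS2 in every library named, as observed, as the mean of 100 simulations with no enrichment against the shared input, and as independent lists would give. The observed overlap in all 3 RAW264.7 libraries is 253, the simulated one 123.3 and the independent one 0.02.

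Between the antibodies the windows of smallest p also held many input tags. Windows near Axin2 (log2 fold change 1.23, SE 0.12), in Cdk8 (1.22, SE 0.13) and near Pex2 (1.2, SE 0.14) had more tags with the C-terminal antibody, with 83, 91 and 48 input tags. A window near Mpzl1 had fewer (-1.9, SE 0.42; limma voom, BH-adjusted p = 0.0306). limma voom called 14 of 86857 windows, 13 higher and 1 lower with the C-terminal antibody, beside 4179 at an unadjusted p under 0.05. Of the 14, only the window near Mir6356 (2.02, SE 0.3) was GPS2-enriched with the C-terminal antibody. With 1 C-terminal library, and N-terminal replicates that differed at these windows themselves (42 and 12 tags near Mir6356, 267 and 156 near Axin2), an antibody difference cannot be told from spread between libraries.

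BMDMs and RAW264.7 cells shared 160 GPS2-enriched windows near 143 genes. Besides the Ccl2 and Jun windows, these included one at -11296 bp from Egr3, an immediate-early gene (195 BMDM tags, ratio 8.97, 5.22 to 16.7; ratios of 5.17, 5.38 and 5.42 in RAW264.7), and the stress-response gene Ier3 (5.67, 2.25 to 18.3). They also included a window at -16196 bp from the inflammasome gene Nlrp3 (6.23, 1.93 to 32), Tnfsf9 (7.09, 1.74 to 62.2), the promoter of the myeloid adaptor gene Tyrobp (5.8, 2.5 to 16.5), an intron of Lrp1 (5.43, 2.48 to 14.1), and a second Tbl1xr1 window at -140628 bp (5.1, 2.71 to 10.6). Cox4i1 (5.88, 2.83 to 14.1), Tfam (8.38, 1.26 to 356) and Actb (7.89, 3.85 to 18.8) were shared as well. Independent lists would share 2.61 windows, and the simulations with a shared input gave 86.4. In WT BMDMs the shared windows carried a median of 482.5 H3K27ac tags and 366.25 H3K4me3 tags, against 68 and 7 over all windows. GPS2 tags in BMDMs correlated by Spearman's rho of 0.61 to 0.62 with those in RAW264.7, of 0.7 with H3K27ac and of 0.35 with H3K4me3, across windows.

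The GPS2-enriched windows were then compared with the rest for histone change. Simulated BMDM libraries with no enrichment gave 302 such windows, beside 996 observed, so some of the set may hold no GPS2. In BMDMs the 957 enriched windows tested for H3K27ac had a median log2 fold change of -0.04 against 0.004 elsewhere, a difference of -0.043. The enriched window at -12757 bp from Ccl2 went the other way, with 0.7. At an unadjusted p under 0.05, 17 of them were higher and 31 lower in GPS2-KO. camera with the preset correlation gave p = 0.0275, lost with an estimated correlation (p = 0.434), and fry gave p = 0.425. Sets of windows matched on level had a median of -0.043, and the GPS2 set lay at their percentile 79.4. For H3K4me3 the 689 enriched windows had a median of -0.011 against 0.016, a difference of -0.028, with 1 higher and 9 lower. camera gave p = 0.0105 with the preset and p = 0.241 with an estimated correlation, and fry gave p = 0.443. The outcome for H3K4me3 depended on the setting: column totals gave fry p = 0.00828 and camera p = 0.0123 with an estimated correlation, and loess scaling gave camera p = 0.0404 with an estimated correlation. A replicate block gave fry p = 0.0346 and camera p = 0.0889 with an estimated correlation. The 58 tested windows enriched at 8-fold had an H3K4me3 difference of -0.108 (fry p = 0.0222, camera p = 0.04 with an estimated correlation). All 1000 level-matched sets had a higher H3K4me3 median, between 0.004 and 0.033. The H3K27ac difference was 0.001 after loess scaling and 0.002 without GPS2-KO replicate 1, and the H3K4me3 difference 0.003 without GPS2-KO replicate 1.

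The marks tended to differ in the same direction, as at Ccl2, Ccl7, Itgam and Fcgr3 (higher for both) and at Lyz2 (lower for both). Of 37515 windows tested for both, 58.4% (exact 95% interval 57.9 to 58.9%) had fold changes of the same sign. Pearson's r was 0.231 and Spearman's rho 0.251 across windows, which are not independent replicates. The interval takes windows as independent and is too narrow, since the 8 fits without 1 library gave 51.8 to 57.8%, all below it. At an unadjusted p under 0.05 in both marks there were 72 windows, 69 with the same sign, where 14.7 would be met if the marks were independent. With 0 windows called in either mark by limma voom, beside 3367 and 454 at an unadjusted p under 0.05 and 0 by limma-trend, the overlap of calls could not be tested. Leaving out H3K4me3 GPS2-KO replicate 1 lowered the share to 51.8%. The excess of windows at an unadjusted p under 0.05 in both marks then vanished, with 78 against 92.8 expected, and without GPS2-KO replicate 2 of H3K4me3 it was 126 against 93.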

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

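Of 246 alternatives over 54 results, 206 gave the same outcome, and 99 of the 246 were chosen after the data were seen. Of the 246, 123 were scalings of the 41 named windows, whose adjusted p left little room for change, so they say little about stability. Planned but not run were the DESeq2 Wald tests and the filter against a WT BMDM input. H3K27ac calls went from 0 to 3720 with a replicate block and 2100 with loess and block, and lay between 0 and 168 when a library was left out. H3K4me3 calls went from 0 to 30 and 67, and stayed at 0 when a library was left out. Replicate numbers are not labelled as pairs: deviations from the group mean correlated at 0.524 between genotypes for H3K27ac (0.519 after loess) and 0.34 for H3K4me3 (0.269), and grouping H3K27ac by number gave 1277 calls. With loess and block 1 list passed fry for H3K27ac, antigen presentation (adjusted p = 0.0408, limma fry with BH). At GPS2-enriched windows the H3K27ac difference of -0.043 stayed -0.043 with column totals (camera p 0.12). It turned to 0.001 with loess and to 0.008 at 8-fold, and ranged from -0.095 to 0.002 without 1 library; it was -0.057 at 2-fold (camera p 0.00245) and -0.068 for windows enriched in both cell types (camera p 0.00015). The H3K4me3 difference of -0.028 was -0.024 at 2-fold (camera p 0.0606) and ranged from -0.051 to 0.003. The share with the same sign in both marks was 54% at windows 4-fold over input, 56.1% with loess, and 51.8 to 57.8% without 1 library. GPS2-enriched windows in BMDMs, RAW264.7 and both numbered 8758, 4796 and 3038 at 2-fold, 122, 10 and 4 at 8-fold, 3666, 4579 and 1740 with background scaling, and 557, 119 and 80 without overlaps. RAW264.7 windows numbered 508 with median-of-ratios scaling and 334 to 341 without 1 N-terminal replicate. Without 1 library the chemokine stretch had a median of 0.49 to 0.8 for H3K27ac and of 0.29 to 1.21 for H3K4me3. The cause of these shifts was not tested.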

Other observations

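H3K27ac windows at an unadjusted p under 0.05 were unevenly spread over the genome. In the 2 Mb bin from 80000001 on chromosome 11, 31 of 78 tested windows were higher in GPS2-KO, most of them around the Ccl2 to Ccl12 genes. In the bin that holds Pparg 20 of 129 were lower, and in the bin of the focal adhesion gene Tns3 13 of 54 were lower.

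The tests with loess scaling, of the flanks and of stromal cells were chosen only after the result at the chemokine genes was seen; that of a single library was set before. GPS2-KO BMDMs might carry more H3K27ac along the Ccl2 to Ccl12 stretch, which was itself picked because it stood out. Its median log2 fold change was 0.69 over 34 windows, and 21 of 80593 runs of equal length were as high. The runs overlap each other, and the 21 can include the stretch and shifted copies of it, so this share is no p-value. From Ccl11 onward GPS2-KO replicate 2 lay close to WT replicate 2 in several windows, as at 81914997 in Ccl12 (15.69 and 14.24 CPM). In others it lay above, as at 81900824 (4.194 and 2.758 CPM). After loess scaling the median of the 34 windows was 0.71, within 3 Mb on either side it was 0.02, and the lowest value with a library left out was 0.49. Uneven scaling, extra copies of the wider region or 1 library alone would not be expected to give these values. The flanks cannot decide on a segment of another strain on chromosome 11, which also holds Gps2, since it need not move their median. The other 2 splits of the 4 libraries gave 0.12 and 0.12, and 3 splits are too few for a share under 0.05. Admixed stromal cells can also express Ccl2. GPS2-KO replicate 2 lay above WT replicate 1 by a median of 0.75 (quartiles 0.55 and 1.14), although its stromal markers were lower by a difference of -0.47. This pair also differs in replicate number, and both levels shifted with that number. Median stromal deviations were 0.26 in WT 1, 0.57 in GPS2-KO 1, -0.6 in WT 2 and -0.21 in GPS2-KO 2. Those of the stretch were -0.42, 0.25, -0.14 and 0.39. Within each number both were higher in GPS2-KO, so a stromal part of any size stays open. Of the 38 windows of the stretch, tested or not, 3 were GPS2-enriched in BMDMs, with H3K27ac log2 fold changes of 0.18, 0.7 and 0.7. The largest log2 fold change, 1.3 at 81859935 in Ccl7, came where GPS2 was 0.598-fold the input. The gain thus did not follow GPS2 enrichment from window to window. With GPS2 enriched at -12757 bp from Ccl2, 1 hypothesis is still that GPS2 restrains this locus. RNA of Ccl2 in labelled separate animals would test it.

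The test of a changed allele was chosen only after the result at Lyz2 was seen; those of Lyz1 and of other macrophage genes were set before. Lyz2 had a median H3K4me3 log2 fold change of -0.64 in 2 windows near its start. H3K27ac there was lower too (-0.38), as a changed allele would give. Lower activity of an intact allele would give this as well, so the value cannot tell them apart. Other macrophage identity genes had an H3K4me3 median of -0.01 near their starts, which speaks against a general loss. Lyz1 had 0 windows near its start, so shared reads could not be tested. The windows near Cpm (116991331, H3K4me3 log2 fold change 3.15) and Mdm1 (117599112, H3K27ac 2.14) lie on the same chromosome 10 as Lyz2 (116717840). Whether they belong to 1 changed segment with Lyz2 was not tested. The values at Lyz2 might reflect a knockout made with a driver inserted there, a hypothesis only, since the labels name no driver. Genotyping of Lyz2 or reads across its start would test it.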
